A study of Mus musculus with 2 samples.

How the data were processed

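Single-nucleus RNA sequencing was made from bone marrow of Plin1-creER; tdTomato mice, per the labels' protocols. In these animals a tamoxifen-inducible Cre recombinase is driven by Plin1, the gene of the lipid droplet coat protein perilipin 1, and Cre activity switches on a red fluorescent reporter. Marrow adipocytes and cells sorted as negative for CD45, Ter119 and CD31 (markers of leukocytes, erythroid cells and endothelium) had been collected 5 weeks after sublethal irradiation and frozen until nuclei were prepared. A total of 4 mice were used, 2 pooled in each of 2 libraries, and both libraries form 1 group, so no treatment was compared. The deposited values are UMI counts per gene and barcode, made with Cell Ranger against the mm10 mouse genome per the submitters' processing notes. The Cell Ranger version, the gene annotation and whether reads in introns were counted are not given in the sources used here. The tables list 32286 features, of which 32158 (99.6%) matched the GENCODE M21 annotation of GRCm38 by gene identifier, and 1 feature is named tdWPRE and is taken here as the reporter transcript. No authors' cell type annotation was used here.

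Library 1 held 6774 barcodes with 11293316 UMIs and a median of 1171.5 per barcode, and library 2 held 7966 barcodes with 12315797 UMIs and a median of 1140. The smallest total of a barcode was 500 UMIs in both. Barcodes with at least 500 UMIs and under 5% mitochondrial UMIs were kept. Doublets were scored with the Scrublet method as provided in scanpy, whose own threshold marked 0 barcodes in library 1 and 1 barcode in library 2 and so had not worked. In its place the highest-scoring 0.8% per 1000 barcodes were removed, 367 barcodes in library 1 and 508 in library 2, a choice made after the data were seen. In all 4752 nuclei of library 1 (70.2%) and 3067 of library 2 (38.5%) were left. The median mitochondrial share of all barcodes was 2.51% in library 1 and 6.01% in library 2, and 4684 barcodes of library 2 were at or above the 5% limit against 1723 of library 1.

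Each library was clustered alone, because clustering them together mostly separated the libraries, which was also decided after the data were seen. Counts were scaled to 10000 per nucleus and log transformed, 2000 variable genes were scaled to at most 10, and 30 principal components, 15 neighbours and the Leiden method at resolution 1 gave 19 clusters in library 1 and 16 in library 2. The 342 genes of the 18 gene lists under test were left out of the clustering. Clusters were named from 20 lists of marker genes. A marker counted as raised when its level in the cluster was above a log2 fold of 1 over the median cluster of its library, with 20 CPM (UMIs scaled to a common total) added to both, and at least 5% of nuclei held it. A name needed at least 3 raised markers and 40% of its list. Any other class had to have under 50% as many raised markers, and the 10 leading genes by fold had to hold no more markers of another class than of the named one. An osteoclast name was not given where Gpnmb led the cluster. A cluster with a median UMI count under the library's median divided by 3 and no marker among its leading genes also stayed unnamed. This rule went through 3 versions. It was settled after the clusters and class counts had been seen and before any differential test. The adipocyte-like class held 343 and 156 nuclei under each version, whereas the marrow stromal-like class held 986 and 828 under the version used and 25 fewer in library 1 under the earlier ones. Clusters that the rule kept out are described with their shares in the results.

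UMI counts were summed per library and class, and the 7 classes with at least 20 nuclei in both libraries gave 14 sums. They were compared with edgeR's quasi-likelihood test, with TMM normalization, filterByExpr, library as a block and Benjamini-Hochberg adjustment at 0.05. All 7 classes shared 1 estimate of the spread. The library numbers pair the sums because all classes of a library came from the same pooled mice. Nuclei are not replicates and n is 2 libraries throughout. The classes were made from the same counts, so p-values are too small for genes that entered the clustering, which 332 of the genes past the threshold did. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, each adjusted over the 18 lists. Fry's first p asks whether the members move one way on balance and its mixed p whether they change in either direction, and neither compares a list with other genes. Log2 values per library used a prior count of 2. Levels are CPM of the class sum. The libraries were also compared by gene length, from start to end in the annotation, over genes with at least 20 UMIs in a class, with 1 CPM added to both. In marrow stromal-like nuclei 12938 of 12947 such genes (99.9%) had a length. Shares of nuclei with a UMI were taken after thinning each nucleus to 500 UMIs, with Wilson 95% intervals, and no nucleus had to be left out. Intervals, and the limit of 3 counts used where a count was 0, cover counting error only. For ratios that rest on 1 to 3 UMIs an exact binomial interval was used.

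The named genes followed a rule: in each list the 2 genes past the threshold with the largest absolute log2 fold change and the same sign in both libraries, or the gene with the smallest p where none passed. To these came the 5 highest and 5 lowest genes past the threshold that were neither used in clustering nor markers, and Plin1, Adipoq, Lepr, Cxcl12, Kitl and Pparg in each class. Of the genes this rule names, 2 are not reported here. The rule, the gene lists, the markers, the tests and most alternatives were fixed before the data were examined. The alternatives fixed then were DESeq2 size factors, DESeq2's own test, no filter on low counts, only the compared classes in the fit, no library block, clustering resolutions of 0.5 and 2, count splitting, doublets kept, at least 1000 UMIs, a mitochondrial limit of 10%, thinned nuclei and each library alone. Those that clustered again, and the joint clustering and matched mitochondrial limit added later, also named clusters without the condition on leading genes, so 2 choices changed together. Alternatives added after the data were seen were joint clustering, adding unnamed stromal clusters to their nearest class, naming without the condition on leading genes, and a mitochondrial limit in library 2 of 9.99%, which removes the same share of barcodes as 5% does in library 1. Comparisons of osteoblast lineage-like and of fibroblast-like with marrow stromal-like nuclei had been planned, but neither class was named in both libraries and they were not run.

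The procedure was tested on simulated sums with known changes for the adipocyte-like against marrow stromal-like comparison, over 11758 genes. edgeR recovered 6.38% of 94 genes changed by a log2 fold of 1 and 59.8% of 92 genes changed by 2, with 1 false call among 62. DESeq2 recovered 3.19% and 33.7%, with 0 false calls among 34. Changes near a log2 fold of 1 were thus mostly missed in the simulation. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5 and igraph 0.11.9.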

Results

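Nuclei of marrow adipocytes and sorted non-haematopoietic cells were profiled in 2 libraries, each from 2 pooled mice aged 13 to 15 weeks, 5 weeks after sublethal irradiation. After filtering, library 1 held 4752 nuclei with 8105594 UMIs and a median of 1184 per nucleus, and library 2 held 3067 nuclei with 5282120 UMIs and a median of 1239. Both libraries belong to the same group, so the comparisons are between classes of nuclei within libraries, and means carry the SD over the 2 libraries. The labels name adipocytes and stromal cells as the material, and the comparison between these classes asks how marrow adipocytes differ from the stromal cells around them after irradiation. Adipocytes were collected beside the sorted cells, so effects of the way of collection and of the class could not be told apart.

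Marrow stromal-like nuclei, named from markers such as Lepr and Ebf3, formed 23.9% ± 4.42 (SD, n = 2) of the nuclei kept. Adipocyte-like nuclei, named from Plin1, Plin4, Cidec and other lipid droplet and lipid metabolism genes, formed 6.15% ± 1.51 (SD, n = 2). They numbered 343 of 4752 in library 1 (7.22%, Wilson 95% interval 6.52 to 7.99) and 156 of 3067 in library 2 (5.09%, 4.36 to 5.92). Although the sort had been set against CD45, Ter119 and CD31, monocyte or macrophage-like nuclei made up 14.3% ± 3.12, endothelial-like nuclei 12.6% ± 1.63 and erythroid-like nuclei 9.27% ± 8.73 (SD, n = 2 each). The erythroid-like share was 15.4% in library 1 and 3.10% in library 2, and its mean was between 3.49% and 5.40% under 6 other settings. Of the 734 erythroid-like nuclei of library 1, 457 lay in a weakly marked cluster with a median of 748 UMIs, in which 5 of 10 erythroid markers were raised, 4 of them haemoglobin genes. Hbb-bs and Hba-a1 led it, followed mostly by uncharacterised genes such as Gm21738, Gm10800 and Gm10719. Joint clustering left 299 nuclei of library 1 with like leading genes unnamed. Adipocytes were collected beside the sorted cells, so these are shares of the collected nuclei and not of the marrow. Plasma-like nuclei formed 2.87% ± 2.99 and pericyte or smooth muscle-like nuclei 0.818% ± 0.503 (SD, n = 2 each), and the plasma-like share was 1.51% at a clustering resolution of 2.

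Neutrophil lineage-like, B lineage-like and T or NK-like nuclei were named in library 1 only, at 16.5%, 4.27% and 3.35%. This depends on the setting: T or NK-like nuclei were also named in library 2 at resolution 2 (131 nuclei) and with a mitochondrial limit of 10% (264 nuclei) or one matched by share of barcodes (248 nuclei), and neutrophil lineage-like nuclei with joint clustering (476 nuclei). In library 2 their markers lay in clusters that also raised markers of another class and stayed unnamed, among them a cluster of 158 nuclei led by S100a8 and S100a9. Unnamed nuclei came to 7.72% in library 1 and 28.0% in library 2. Library 2 held 2 unnamed clusters with 10 of 11 marrow stromal markers raised. One, of 90 nuclei (2.93%), also raised 5 osteoblast lineage markers and was led by Col1a1, with Bglap, the osteoblast product osteocalcin, among its leading genes. The other, of 133 nuclei (4.34%), was led by Igfbp7, Bgn and Adipoq. With both added to the marrow stromal-like class, 651 genes were higher and 928 lower in adipocyte-like nuclei, against 610 and 777 without them.

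**Figure D1:**
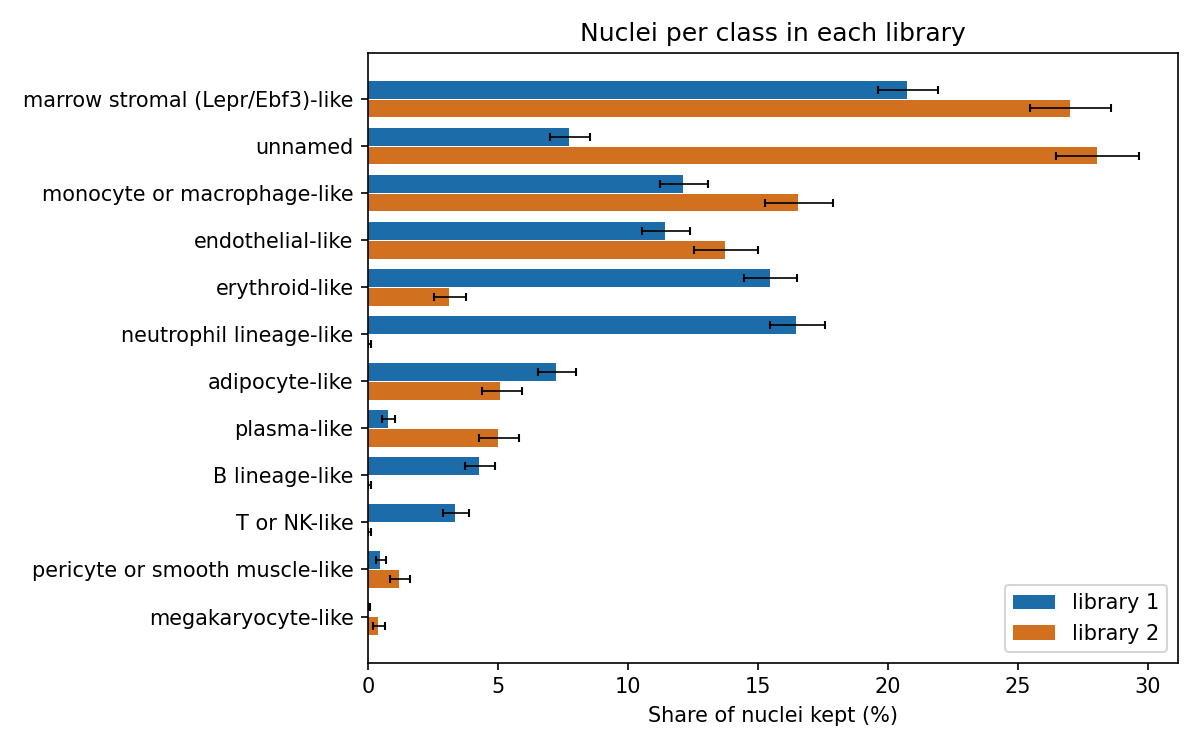
Share of the nuclei kept in each class (percent, bars) in library 1 and library 2, with Wilson 95% intervals for counting error. Marrow stromal-like nuclei formed 20.7% and 27.0%, adipocyte-like nuclei 7.22% and 5.09%.

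Long genes were far lower in library 2 than in library 1 in each of the 4 classes examined. In marrow stromal-like nuclei the median log2 ratio of library 2 to library 1 was 1.18 for the shortest decile of genes and -3.53 for the longest decile, a difference of -4.71. The difference was -6.51 in adipocyte-like, -5.98 in endothelial-like and -5.93 in monocyte or macrophage-like nuclei. Each class had deciles of its own genes, 12938 in marrow stromal-like and 6922 in adipocyte-like nuclei. The longest decile had a median length of 282327 and 410447 bases in these 2 classes, so the sizes cannot be ranked between classes. Across genes, which are not independent replicates, the Spearman correlation of this ratio with gene length lay between -0.74 and -0.82. This comparison was chosen after the data were seen. The nuclear long noncoding RNA Malat1, chosen after the trend and before its own values were seen, was at 18735 CPM in marrow stromal-like nuclei of library 1 and 45637 in library 2. Its log2 ratio there, 1.28, was close to the 1.18 of the shortest decile of genes. Pparg, the master regulator of fat cell differentiation and a long gene, was at 1796 CPM in adipocyte-like nuclei of library 1 and 142 in library 2. Levels and SDs set across the libraries carry this difference, whereas fold changes between classes are taken within libraries. For adipocyte-like over marrow stromal-like nuclei, the median log2 fold change of the longest decile of genes lay above that of the shortest decile by 0.22. The difference was 0.37 in library 1 alone and 0.006 in library 2 alone, where the longest decile and all genes had a median of 0. A gene with no UMI in either class gives exactly 0 in a single library. The library 2 value thus cannot show that length has no effect there.

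**Figure D2:**
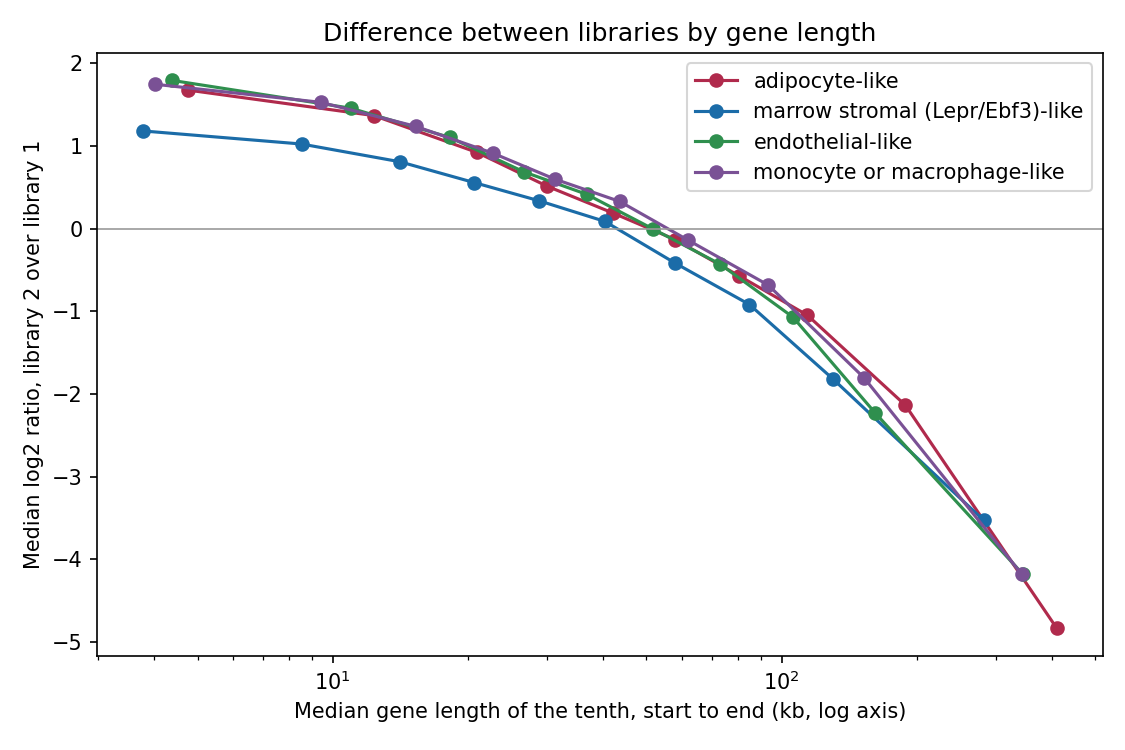
Median log2 ratio of CPM in library 2 over library 1 (vertical axis) for deciles of genes by length (horizontal log axis, kb), in 4 classes of nuclei. The ratio falls with length in each class, and the longest minus the shortest decile is -4.71 in marrow stromal-like and -6.51 in adipocyte-like nuclei.

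Plin1 (ENSMUSG00000030546, chromosome 7, 79720218 to 79732903 on the minus strand of GRCm38) marked adipocyte-like nuclei, at 311.8 ± 64.7 CPM against 6.99 ± 1.69 in marrow stromal-like nuclei (SD, n = 2 each). It is a marker used to name the class. The feature tdWPRE was also highest there, at 219 CPM in library 1 and 1478 in library 2, against 106 and 261 in marrow stromal-like, 94.4 and 332 in endothelial-like and 55.9 and 148 in monocyte or macrophage-like nuclei. In nuclei thinned to 500 UMIs, 12.0% of adipocyte-like nuclei of library 1 and 46.8% of library 2 held a tdWPRE UMI. In blood cell classes with at least 20 nuclei this share ran from 1.74% to 5.56% in library 1 and from 1.05% to 9.80% in library 2. This leaves out 11 megakaryocyte-like nuclei of library 2 for their number, here and below. Their median depth was 4783 UMIs, and after thinning 9.09% held a UMI of tdWPRE, 9.09% of Adipoq, 9.09% of Lepr, 72.7% of Cxcl12 and 0 of 11 of Kitl, which allows a share of up to 27.3%.

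Adipoq (chromosome 16, 23146536 to 23158028, plus strand), the gene of the fat hormone adiponectin, did not differ detectably between adipocyte-like and marrow stromal-like nuclei. Its level was 242 ± 105 CPM in adipocyte-like and 266 ± 23.4 in marrow stromal-like nuclei (SD, n = 2 each). The log2 fold change was -0.32 (SE 0.37, adjusted p = 0.77, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and it was -0.72 in library 1 and 0.38 in library 2. In library 2 the marrow stromal-like class leaves out the unnamed clusters of 90 and 133 nuclei with stromal markers, at 1124 and 1252 CPM. In library 1 it includes a cluster of 25 nuclei at 1484 CPM. The library 2 value thus depends on where these clusters are placed. After thinning, 9.74% ± 2.45 of marrow stromal-like and 8.31% ± 1.85 of adipocyte-like nuclei held an Adipoq UMI (SD, n = 2 each). In blood cell classes with at least 20 nuclei, with median depths of 863.5 to 1211 UMIs, the share was 0% to 5.03% in library 1 and 3.94% to 8.42% in library 2. The highest Adipoq level among them was 72.9 CPM in library 1 and 301 CPM, in erythroid-like nuclei, in library 2. Plasma-like and monocyte or macrophage-like nuclei of library 2 were at 97.7 and 83.9 CPM. The median depth was 1594 and 1582.5 UMIs in adipocyte-like and 1429.5 and 1342 in marrow stromal-like nuclei. Without thinning the shares were 27.7% in adipocyte-like and 25.7% in marrow stromal-like nuclei.

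Cxcl12 (chromosome 6, 117168535 to 117181367, plus strand), Kitl (chromosome 10, 100015630 to 100100416, plus strand) and Lepr (chromosome 4, 101717404 to 101815352, plus strand) were higher in marrow stromal-like nuclei. Cxcl12 and Kitl encode secreted factors that retain and sustain haematopoietic stem cells, and Lepr encodes the leptin receptor. In adipocyte-like nuclei the log2 fold change was -2.42 for Cxcl12 (adjusted p = 1.9e-05), -2.13 for Kitl (adjusted p = 1.3e-05) and -3.71 for Lepr (adjusted p = 1.1e-12), all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and in both libraries. Lepr had named the stromal class and entered the clustering. Cxcl12 stood at 9615 ± 4749 CPM in marrow stromal-like and 2162 ± 1735 in adipocyte-like nuclei (SD, n = 2 each). Its level in adipocyte-like nuclei, 935 and 3389 in libraries 1 and 2, was close to that in endothelial-like nuclei, 882 and 3275, and in monocyte or macrophage-like nuclei, 755 and 3172. The thinned share of adipocyte-like nuclei with a Cxcl12 UMI, 34.1% and 74.4%, lay within the blood cell range of 32.7% to 44.8% in library 1 and 71.9% to 74.7% in library 2, and is read as background. Lepr at 4.96% and 10.3% did not exceed the blood cell ranges of 2.52% to 8.17% and 12.6% to 20.3%. The share with a Kitl UMI in library 1 was 16.6% of adipocyte-like nuclei (Wilson 95% interval 13.1 to 20.9), against at most 10.2% (8.02 to 13.0) in a blood cell class. In library 2 it was 14.1% (9.50 to 20.4) against at most 12.6% (10.0 to 15.8), a difference within counting error. Kitl was at 449 ± 92.3 CPM there against 2002 ± 627 in marrow stromal-like nuclei (SD, n = 2 each).

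**Figure D3:**
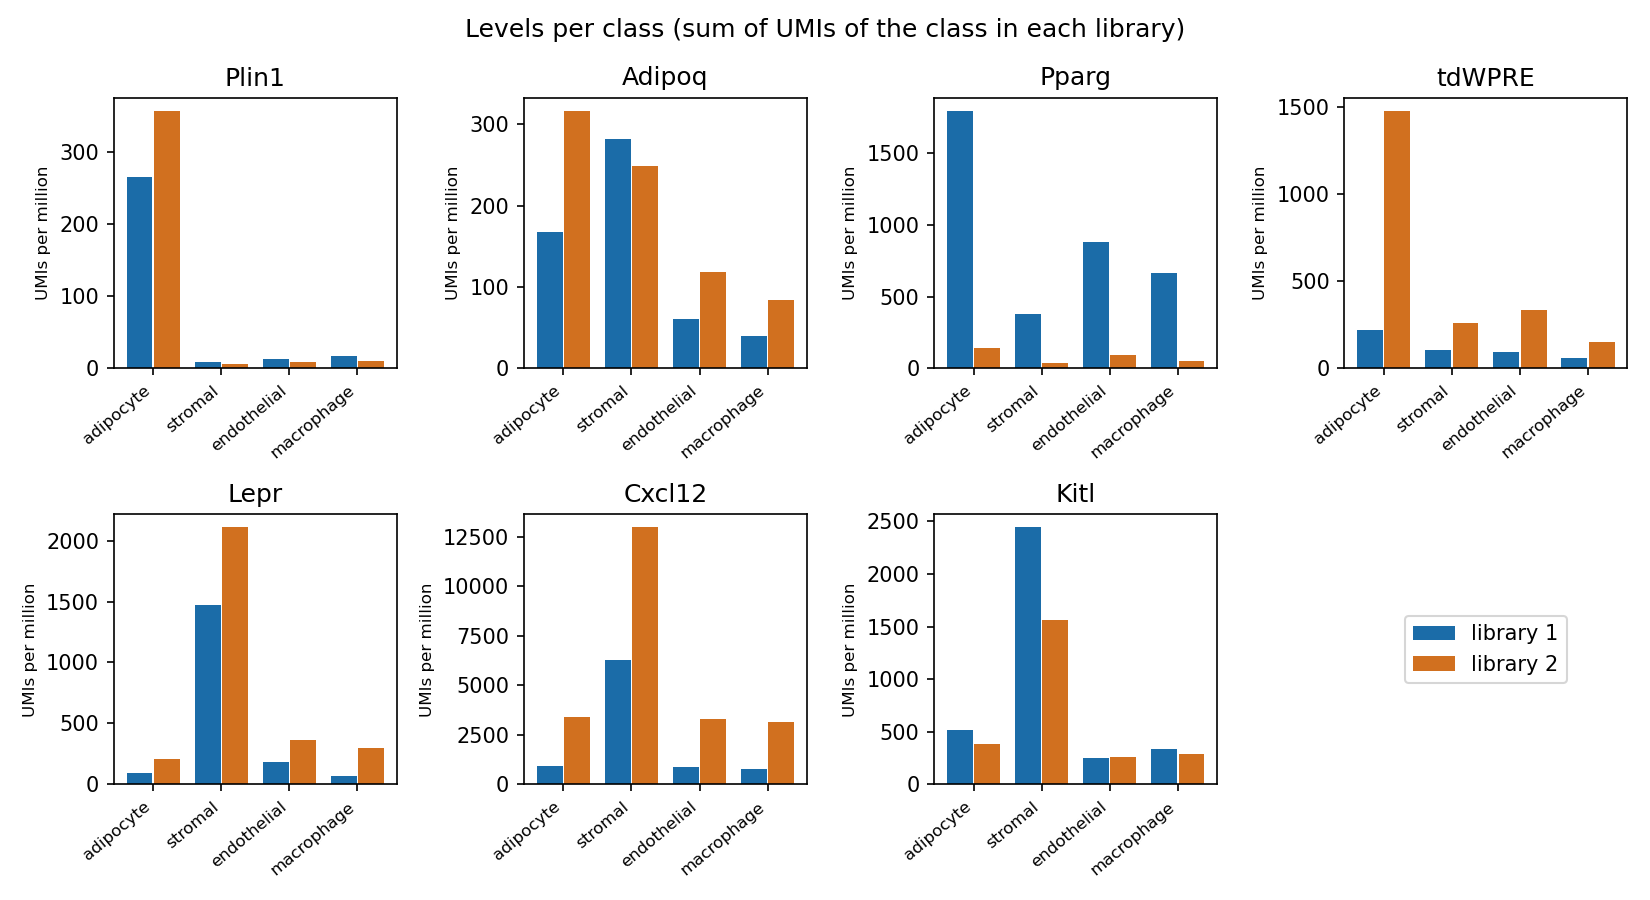
CPM (bars) of 7 genes or features in adipocyte-like, marrow stromal-like, endothelial-like and monocyte or macrophage-like nuclei of each library. Plin1 stood out in adipocyte-like nuclei at 266 and 358, Cxcl12 in marrow stromal-like nuclei at 6258 and 12973, while Adipoq was at 282 and 249 in marrow stromal-like nuclei.

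Genes of fat storage and release were higher in adipocyte-like than in marrow stromal-like nuclei. Of 15 lipolysis genes tested, 13 rose and none fell, led by Lipe, the hormone-sensitive lipase (log2 fold change 5.12, SE 0.42, adjusted p = 1.5e-22, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Pde3b, the phosphodiesterase through which insulin restrains lipolysis (4.95, SE 0.44). Lipe stood at 820 ± 394 CPM against 23.5 ± 7.74 (SD, n = 2 each). Of 13 triglyceride synthesis and lipid droplet genes, 8 rose and none fell, with Gpd1, which supplies glycerol 3-phosphate, at a log2 fold change of 4.38 (3.67 in library 1 and 4.55 in library 2) and Fitm2, a lipid droplet formation gene, at 3.22. Adjusted over the list alone, 13 lipolysis and 9 triglyceride genes rose. Both lists passed camera (adjusted p = 4.1e-17 and 1.6e-09) and passed with an estimated correlation, each at adjusted p = 0.0196.

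De novo lipogenesis rose in 9 of 16 genes with none falling, also 9 adjusted over the list alone, including Thrsp, a lipogenic regulator (log2 fold change 4.82, with 4.04 in library 1 and 5.21 in library 2), and Mlxipl, the carbohydrate-responsive transcription factor ChREBP (4.11, with 3.22 and 4.35). Its camera adjusted p was 5.1e-06, but the call was lost with an estimated correlation (adjusted p = 0.058 with an estimated correlation). Fatty acid oxidation and thermogenesis rose in 5 of 16 genes and in 6 adjusted over the list alone, with Ppargc1a, a coactivator of mitochondrial genes, at a log2 fold change of 3.61 (2.95 in library 1 and 3.87 in library 2). That list passed camera both ways (adjusted p = 2.9e-05, and 0.0243 with an estimated correlation). Among 14 fatty acid uptake and binding genes 6 rose and 1 fell, also when adjusted over the list alone. Acsl1, which activates long-chain fatty acids, had a log2 fold change of 5.33 (SE 0.45) and Fabp4, a fatty acid binding protein, one of 4.33. The list had a camera adjusted p of 0.0164 and an adjusted p = 0.161 with an estimated correlation. Fabp4 was also at 1055 and 5428 CPM in endothelial-like nuclei.

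Insulin signalling and glucose uptake rose in 9 and fell in 2 of 18 genes, and in 11 and 3 adjusted over the list alone. Slc2a4, the insulin-responsive glucose transporter GLUT4, rose by a log2 fold change of 4.00 (SE 0.55), with 2.10 in library 1 and 4.52 in library 2. The camera adjusted p was 3.6e-04 (adjusted p = 0.0825 with an estimated correlation). Of 11 adipokine and adipocyte hormone genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone), among them Nrg4 (log2 fold change 4.89, SE 0.45, with 3.81 in library 1 and 5.51 in library 2) and Cfd, which encodes the complement protease adipsin (3.90, SE 0.42). The camera adjusted p of this list was 8.4e-04 (adjusted p = 0.146 with an estimated correlation), and with clusters and test taken from separate parts of each count it was 0.27. Of 18 adipogenic transcription factors 3 rose and 3 fell (7 and 5 adjusted over the list alone), without a shift of the list (camera adjusted p = 0.509, and 0.534 with an estimated correlation). Pparg rose by 2.16 (SE 0.40, adjusted p = 7.4e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), by 2.25 in library 1 and 1.92 in library 2, and Cebpd, an early adipogenic factor, fell by 2.40. In libraries 1 and 2 Pparg was at 379 and 35.6 CPM in marrow stromal-like nuclei. It was higher in endothelial-like nuclei, at 878 and 91.8, and in monocyte or macrophage-like nuclei, at 664 and 52.5.

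**Figure D4:**
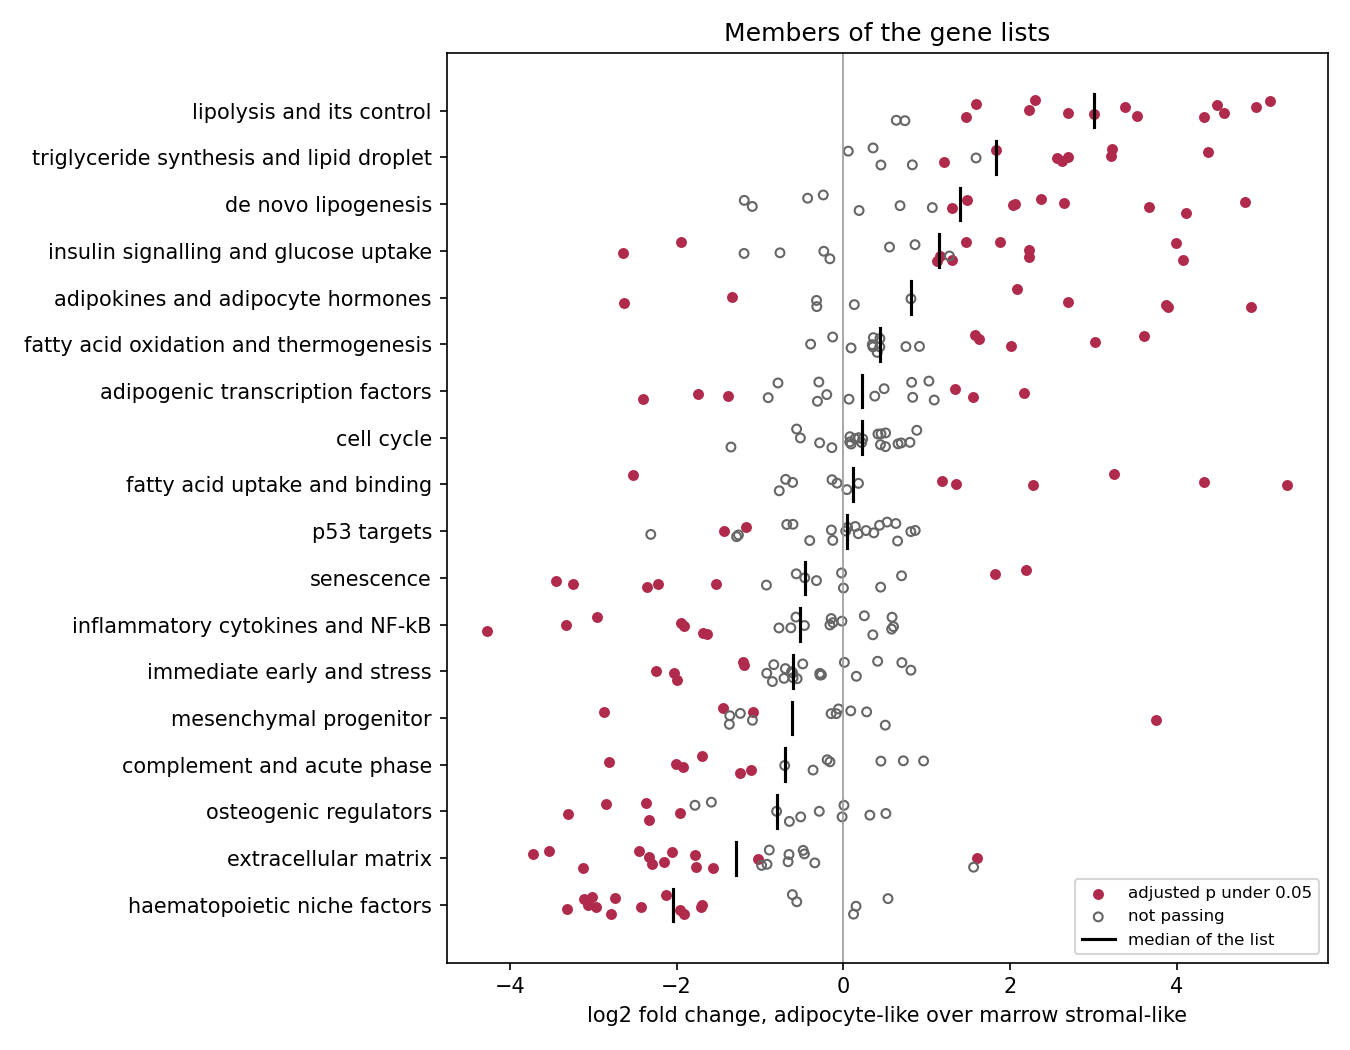
Log2 fold change of adipocyte-like over marrow stromal-like nuclei (horizontal axis) for each tested member of the 18 gene lists. Filled points passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, open points did not, and bars mark list medians, which run from -2.05 for haematopoietic niche factors to 3.01 for lipolysis.

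Of 18 haematopoietic niche factors, 13 fell in adipocyte-like nuclei and none rose, also 13 adjusted over the list alone. Bmp4, a secreted growth factor, fell by 3.11 on the log2 scale (SE 0.55, adjusted p = 1.9e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), from 83.5 ± 6.94 CPM in marrow stromal-like to 9.67 ± 2.13 in adipocyte-like nuclei (SD, n = 2 each), and its log2 fold change was -3.00 in library 1 and -2.44 in library 2. Bmp4 was at 8.32 and 16.5 CPM in monocyte or macrophage-like and at 22.1 and 69.3 CPM in endothelial-like nuclei. Ccl19, a chemokine, had 1 UMI in adipocyte-like against 45 in marrow stromal-like nuclei, a ratio of 13.0 with a counting interval of 2.22 to 526, and its call (adjusted p = 0.0399) was lost with size factors by median of ratios (0.0506) and with doublets kept (0.0509). Its log2 fold change was -1.17 in library 1 and -2.98 in library 2. The list had a camera adjusted p of 4.8e-06 (adjusted p = 0.146 with an estimated correlation).

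Extracellular matrix genes fell in 12 and rose in 1 of 22, and fell in 15 and rose in 2 adjusted over the list alone. Tnc, which encodes tenascin C, fell by 3.72 on the log2 scale (SE 0.44) and Col8a1, a collagen gene, fell by 3.54 (SE 0.43). In libraries 1 and 2 the log2 fold change was -4.16 and -2.90 for Tnc and -4.09 and -2.59 for Col8a1. In adipocyte-like nuclei Tnc was at 83.2 and 276 CPM, against 94.4 and 387 in endothelial-like and 96.3 and 267 in monocyte or macrophage-like nuclei. Col8a1 was at 78.3 and 101 CPM, against 119 and 130 and 95.1 and 100 in these classes. Levels so alike may be background. The list's camera adjusted p was 5.5e-06 (adjusted p = 0.161 with an estimated correlation). Osteogenic regulators fell in 5 of 15 genes and rose in none, with 6 falling adjusted over the list alone. Tnfsf11, which encodes the osteoclast-inducing cytokine RANKL, fell by 3.31 (SE 0.42), from 335 ± 12.6 to 35.4 ± 13.1 CPM (SD, n = 2 each). In libraries 1 and 2 it was at 26.1 and 44.7 CPM in adipocyte-like and 28.0 and 42.8 in endothelial-like nuclei. In monocyte or macrophage-like nuclei it was at 8.32 and 55.5 CPM, so the adipocyte-like level may be background. Sp7, the osteoblast transcription factor osterix, fell by 2.85 (SE 0.71) on 4 UMIs in adipocyte-like nuclei, with -2.74 in library 1 and -1.77 in library 2. The osteogenic list passed camera at both settings (adjusted p = 2.0e-04, and 0.0250 with an estimated correlation). Of 14 mesenchymal progenitor genes 3 fell and 1 rose, also adjusted over the list alone, without a shift of the list (camera adjusted p = 0.202, and 0.480 with an estimated correlation). Snai2, an epithelial to mesenchymal transition factor, fell by 2.87 (-2.26 in library 1 and -3.17 in library 2), whereas Mcam, which encodes the adhesion molecule CD146, had a log2 fold change of 3.75 (3.12 and 3.40) and was also at 35.0 and 161 CPM in endothelial-like nuclei.

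Some members of 3 inflammatory, stress and complement gene lists fell in adipocyte-like nuclei. Whether these falls belong to the class or to the separate collection of adipocytes and sorted cells could not be told. Inflammatory cytokines and NF-kB fell in 7 of 20 genes and rose in none, also 7 adjusted over the list alone (camera adjusted p = 0.0162, but adjusted p = 0.425 with an estimated correlation). Il6 fell by 4.28 on the log2 scale (SE 0.60), with 5 UMIs in adipocyte-like and 414 in marrow stromal-like nuclei, and Ccl2, a monocyte attractant, fell by 3.33 (SE 0.54). In libraries 1 and 2 the log2 fold change of Il6 was -3.00 and -4.48. In monocyte or macrophage-like nuclei of libraries 1 and 2 Il6 was at 122 and 186 CPM, against 61.7 and 249 in marrow stromal-like nuclei, and Ccl2 at 68.9 and 282 CPM, against 27.8 and 253. Immediate early and stress genes fell in 5 of 23, also 5 adjusted over the list alone, including the transcription factors Nr4a3 (fell by 2.25) and Egr3 (fell by 2.03), with a camera adjusted p of 5.6e-04 (adjusted p = 0.252 with an estimated correlation). Nr4a3 was at 403 and 321 CPM in monocyte or macrophage-like and 237 and 380 CPM in marrow stromal-like nuclei. Complement and acute phase genes fell in 6 of 13, also 6 adjusted over the list alone, with the protease inhibitor Serpina3g falling by 2.82 and the complement protease C1s1 falling by 2.00. The camera adjusted p was 0.0359 (adjusted p = 0.425 with an estimated correlation).

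Senescence genes fell in 5 and rose in 2 of 15, and fell in 6 and rose in 2 adjusted over the list alone, with a camera adjusted p of 0.303 (0.531 with an estimated correlation). Timp1, a metalloproteinase inhibitor, had 3 UMIs in adipocyte-like and 136 in marrow stromal-like nuclei, a ratio of 13.1 with a counting interval of 4.40 to 64.5, and Mmp13, a collagenase, fell by 3.24 (SE 0.42). The log2 fold change of Timp1 was -3.44, with -2.38 in library 1 and -2.87 in library 2. Mmp13 in adipocyte-like nuclei, at 55.5 and 328 CPM, was close to its 74.6 and 320 CPM in endothelial-like nuclei and may be background. Of 22 p53 targets, 2 fell and none rose, also adjusted over the list alone: Polk, a DNA polymerase, fell by 1.43 (SE 0.50, adjusted p = 0.0426) and Cdkn1a, the cell cycle inhibitor p21, by 1.17 (SE 0.38, adjusted p = 0.0271), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Both calls were lost with DESeq2 (adjusted p = 0.153 and 0.0960) and without the filter on low counts (0.0555 and 0.0504), that of Polk also with size factors by median of ratios (0.0541) and that of Cdkn1a with count splitting (0.0861). Polk had 18 adipocyte-like UMIs in library 1 and 1 in library 2, with log2 fold changes of -1.05 and -2.44. The list's median was 0.04 while camera pointed down, with an adjusted p of 0.960 at both settings. No cell cycle gene of 21 passed, also adjusted over the list alone (camera adjusted p = 0.368, and 0.754 with an estimated correlation), and Mki67, the proliferation marker with the smallest p, had a log2 fold change of 0.80 (SE 0.43, adjusted p = 0.309), with 1.08 in library 1 and 0.15 in library 2. By fry's directional test, de novo lipogenesis, insulin signalling, niche factors, extracellular matrix, adipokines, fatty acid uptake, immediate early and inflammatory genes all passed (adjusted p from 3.7e-04 to 0.0409), and complement did not (adjusted p = 0.0775). By fry's mixed test each list passed except cell cycle (adjusted p = 0.553).

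Among genes neither used in clustering nor markers, the highest past the threshold was Il17re, an interleukin-17 receptor chain, at a log2 fold change of 5.36 (SE 0.66, adjusted p = 1.2e-11, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 60 UMIs in adipocyte-like and 5 in marrow stromal-like nuclei. Next came Acsl1 and Lipe, described above with their lists, then Ppp1r1a, an inhibitor of protein phosphatase 1, at 5.09 (SE 0.70) with 50 and 5 UMIs, and Pde3b. In libraries 1 and 2 the log2 fold change was 3.38 and 4.47 for Il17re and 2.88 and 4.61 for Ppp1r1a. Values of single libraries carry a prior count of 2, which draws genes with few UMIs toward 0. The 5 lowest had no UMI in adipocyte-like nuclei. Taking 3 counts over both libraries as the limit, Dzip1l was at least 6.67-fold lower, Maged2 at least 6.18-fold, Fzd2 (a Wnt receptor) at least 4.44-fold, AU015336 at least 3.86-fold and Apol8 at least 3.57-fold lower. The calls for AU015336 and Apol8 were lost with doublets kept (adjusted p = 0.0582) and at a mitochondrial limit of 10% (0.115), respectively.

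In all, 12656 genes were tested, and 610 were higher and 777 lower in adipocyte-like than in marrow stromal-like nuclei at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of these 1387 genes, 1370 had the same sign in both libraries. In libraries 1 and 2 the class sums of adipocyte-like nuclei held 612641 and 268529 UMIs and those of marrow stromal-like nuclei 1831866 and 1208403. Without the library block no gene passed in either direction, while 210 were higher and 232 lower at an unadjusted p under 0.05, and DESeq2 with the block called 565 higher and 551 lower. With each nucleus thinned to 500 UMIs, 354 were higher and 449 lower among 7709 genes tested. Osteoblast lineage-like and fibroblast-like nuclei were not compared with marrow stromal-like nuclei, because neither class was named in both libraries.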

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

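Joint clustering, the added stromal clusters, naming without the condition on leading genes and the matched mitochondrial limit were chosen after the data were seen. The count of 610 higher and 777 lower genes stayed within 1.5 times, in each direction, under 14 other settings, and genes called both ways had the same direction each time. It did not in 2: thinned nuclei, with fewer UMIs and genes tested, gave 354 and 449, and the fit with no replicate block gave 0 and 0. The block pairs classes of the same mice and also takes up differences that the classes of a library share, such as the one by gene length. In a fit with no block edgeR's common dispersion was 0.710 against 0.0488. Without either library no residual degrees of freedom were left, so only fold changes could be had. The median log2 fold change of all genes was -0.06 with TMM, 0.01 with median of ratios and 0.06 with DESeq2, which gave no adjusted p for 2699 genes. An estimated correlation left 4 of 13 gene list calls. Count splitting turned the cell cycle list downward (adjusted p = 0.973). Of 711 tested values of named genes under alternatives, 655 kept their direction and side of the threshold, 55 lost the call, 45 of these without the block, and 1 reversed. Of 94 values from a single library, 93 kept the direction, 32 of them more than 1.5 times in fold from the joint value, and 1 reversed. Single-library values carry a prior count of 2, which draws genes with few UMIs toward 0. Part of these gaps from the joint value may stem from that and not from a difference between libraries. Adipoq reversed without library 1 (its log2 fold change ran from -0.72 to 0.38 with a library left out) and Mki67 with doublets kept (-0.066). Their causes were not tested.

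The adipocyte-like share was 8.01% at a minimum of 1000 UMIs. The endothelial-like share was 15.9% at resolution 2, 14.8% with doublets kept and 10.5% at 1000 UMIs. The marrow stromal-like share was 30.7% with a mitochondrial limit of 10% and 28.4% with the matched limit. The erythroid-like share was 5.34% at resolution 0.5, 5.14% with count splitting, 4.56% with doublets kept, 3.49% at 1000 UMIs, 4.32% with a limit of 10% and 5.40% with joint clustering, each over 1.5 times below its 9.27% and within the SD between libraries. The plasma-like share was 1.51% at resolution 2, against 2.87%. The causes were not tested. No mean was taken where a class was named in 1 library only. This held for monocyte or macrophage-like nuclei at resolution 0.5 (15.5% in library 2) and with joint clustering (14.8% in library 1), for plasma-like nuclei at resolution 0.5, with doublets kept and with either other mitochondrial limit, and for pericyte or smooth muscle-like nuclei at 1000 UMIs. Without thinning, which leaves more UMIs per nucleus, the shares of adipocyte-like and marrow stromal-like nuclei with a UMI were 35.8% and 1.03% for Plin1, 27.7% and 25.7% for Adipoq, 20.3% and 76.3% for Lepr, and 34.0% and 78.1% for Kitl. They were 83.6% of adipocyte-like nuclei for Cxcl12 and 19.5% of marrow stromal-like nuclei for tdWPRE. The planned osteoblast lineage-like and fibroblast-like comparisons and their alternatives were not run, because neither class was named in both libraries. Depth limits genes with few UMIs, such as the 5 lowest, which had none in adipocyte-like nuclei.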

Other observations

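The tests of tdWPRE, of Adipoq and of free RNA between libraries were chosen only after the result was seen, and so were the matched mitochondrial limit and the clusters described here. A cluster led by Gpnmb, Mmp12, Mmp19 and Atp6v0d2 was found in each library. It held 167 nuclei (3.51%) in library 1 and 120 nuclei (3.91%) in library 2, and it stayed unnamed because it raised as many monocyte or macrophage markers as osteoclast markers, 4 of each. Gpnmb encodes a transmembrane glycoprotein of macrophages and osteoclasts, and Atp6v0d2 a subunit of the vacuolar proton pump. Gpnmb stood at 1460 CPM in this cluster of library 1 and at 1947 in library 2. In the monocyte or macrophage-like clusters it was 62.8 and 47.7 in library 1 and 257 and 246 in library 2. Mmp12, a macrophage elastase, was at 1654 and 4039 in the 2 clusters. Library 2 also held 16 nuclei led by Ctsk, the cathepsin of bone resorption, in which 6 of 6 osteoclast markers were raised, and which stayed unnamed because 3 B lineage markers were raised too.

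Marrow stromal-like clusters differed in the secreted genes they carried. In library 1, a small cluster of 25 nuclei led by Mgp, Cxcl14 and Spp1 had 24152 CPM of Cxcl12 and 1484 of Adipoq, against 7013 and 335 in the largest stromal cluster of 571 nuclei and 3568 and 96.2 in another of 390 nuclei. In library 2, the unnamed clusters of 90 and 133 nuclei with stromal markers had 29101 and 22804 CPM of Cxcl12 and 1124 and 1252 of Adipoq, against 12973 and 249 in the 828 marrow stromal-like nuclei. The complement inhibitor gene Serping1 was at 1484, 1495 and 1330 CPM in these 3 clusters and at 184 to 392 in the larger ones. Of these 3, the cluster of 25 had a median of 675 UMIs and a median mitochondrial share of 3.88%, against 1671 UMIs and 2.44% in the cluster of 571 and 1091 UMIs and 2.31% in that of 390. The cluster of 133 had 658 UMIs and 3.97%, and that of 90 had 3910 UMIs and 3.18%, against 1342 UMIs and 3.05% in the 828 nuclei. These are descriptions of clusters made from the same counts, with no test across libraries.

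Adipoq UMIs were present in marrow stromal-like nuclei, at 282 and 249 CPM, although the class was named from Lepr and Ebf3. In library 1 the levels argue against free RNA as the whole of it in the stromal clusters of 571 and 25 nuclei, at 3.20 times (counting interval 2.33 to 4.50) and 14.2 times (8.51 to 23.3) the highest cluster of another named class, the weakly marked erythroid-like one of 457 nuclei, but not in the cluster of 390 nuclei, at 0.918 times (0.594 to 1.42), where it stays open. In library 2 free RNA stays open for the 828 named marrow stromal-like nuclei. Their level was 2.11 times (1.59 to 2.84) that of endothelial-like nuclei but 0.826 times (0.591 to 1.18) that of erythroid-like nuclei. The erythroid-like level rested on 39 UMIs held by 15 of 95 nuclei. Pericyte or smooth muscle-like nuclei of library 2 were lower, at 182 CPM, as were plasma-like nuclei at 97.7 and monocyte or macrophage-like nuclei at 83.9. The erythroid-like level was 301 CPM, and it was 334 CPM in the unnamed cluster led by S100a8. That cluster also raised 7 marrow stromal markers and held 9904 CPM of Cxcl12. The unnamed stromal clusters of 90 and 133 nuclei, left out of this comparison, stood at 1124 and 1252 CPM of Adipoq. Adipocyte nuclei or doublets among the stromal nuclei would bring the adipocyte markers along, but the ratio of marrow stromal-like to adipocyte-like levels was at most 0.0260 times as large for the adipocyte markers as for Adipoq in either library. Transcription of Adipoq by stromal cells may account for it, but no biological explanation was tested.

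The reporter feature tdWPRE was also found outside adipocyte-like nuclei. RNA set free from adipocytes would keep it and the adipocyte markers in 1 ratio in every class. That ratio differed between the highest and lowest of 3 classes by 2.33 times in library 1 (1.69 to 3.28). In library 2 the difference was 2.18 times (1.74 to 2.76). It rests on monocyte or macrophage-like nuclei, the lowest in libraries 1 and 2 at 0.290 and 1.03. Marrow stromal-like (0.676 and 2.25) and endothelial-like nuclei (0.491 and 1.90) lay closer together. Without the macrophage-like class the test would not argue against RNA from adipocytes. In adipocyte-like nuclei the ratio was 0.0555 and 0.261. A like background in all droplets would give like levels, and marrow stromal-like over endothelial-like nuclei, compared first, gave 1.12 times (0.861 to 1.47) in library 1 and 0.784 times (0.647 to 0.954) in library 2. Monocyte or macrophage-like nuclei were added to this comparison after their lower values had been seen, and the highest of the 3 classes was then at least 1.90 times the lowest (1.37 to 2.67). Without them, levels over the other named classes with at least 20 nuclei, adipocyte-like left out, still differed beyond counting error in each library (p = 0.0001 by chi-square, the smallest that 10000 simulated draws from 1 common level can give), which argues against a like level but not against free RNA in unequal amounts. Free RNA from several sources, or low transcription of the feature in other cells, may remain, and no biological explanation was tested.

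The libraries differed within every class examined, and a counting difference may account for part of it. The log2 ratio of library 2 to library 1 lay lower in the longest than in the shortest decile of genes, with a difference of -4.71 in marrow stromal-like nuclei. In the other classes, whose deciles hold other genes, the difference was between -5.93 and -6.51. Reads from introns counted in library 1 and not in library 2 would give this, since long genes are mostly intron. The nuclear transcripts Malat1 and Neat1, which are made mostly of exon, were higher in library 2, at a median log2 ratio of 1.41 over 4 classes. This goes with that hypothesis, though it rests on 2 genes. The value also lay within the range of the shortest decile of genes given below, so it does not single that hypothesis out. More cytoplasmic RNA in library 2 needed a value under -1 and also met 1.41. The shortest decile of genes rose too, by 1.18 to 1.79 over the 4 classes. Such a shift, if counting caused it, could mask a fall of these transcripts, so the test cannot decide on cytoplasmic RNA. More free RNA in library 2 stays open too: stromal transcripts outside stromal nuclei, relative to the stromal level, were at least 1.83 times as high as in library 1, though whether the counting difference moves this ratio was not tested. In named macrophage-like nuclei of library 2, 84.2% held such a UMI against 92.3% from an even spread, or 91.3% of it. This argues against doublets as the main source there. Clusters that raised markers of a second class had been left unnamed. Doublets in those clusters, or doublets on top of a background, could not be told by this test. The same counting difference could raise mitochondrial shares in library 2, and with the limit matched by share of barcodes and naming without the condition on leading genes 629 genes were higher and 998 lower in adipocyte-like nuclei, against 624 and 897 with that naming alone, and no biological explanation was tested because both libraries form 1 group.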
